A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

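RNA of Saccharomyces cerevisiae exposed to thorium (Cy5) and of untreated cells (Cy3) was measured on 2-colour arrays, in 3 hybridizations from independent biological samples per the series' design text. Each hybridization was scanned at high and at low laser power, to recover spots beyond the scanner's range, per the labels. Per the labels, spots with a flag of 0 entered a LOWESS normalization, and the scans of a hybridization were merged in GeneSpring; versions, the scanner, the image software and the background step are not given in the sources used here. The deposited values are read as log2 ratios per spot and scan. The table states neither the base of the logarithm nor the direction. Base 2 was assumed, and the direction was taken as Cy5 over Cy3 from the order of the channels. With another base the folds would differ and the test results would not. The merged values are not used here.

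LOWESS centres each scan, so a change shared by most genes cannot be seen. Scan medians ran from -0.16 to 0.01, and the SD of the ratios from 0.61 to 1.05. Values were kept for 60.7%, 79.3% and 78.6% of probes in the high power scans of replicates 1, 2 and 3, and for 40.2%, 54.7% and 65.9% in the low power scans. Signal intensities were not used here, so the brightness behind a ratio is unknown.

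Of 6912 probes 5513 carried 1 gene name in the platform annotation, 1399 are unnamed here and 0 carried several. Names were matched by Entrez ID to the reference gene table (assembly R64) for 5360 of 5365 genes, and the other 5 kept their name. Of 99 genes with more than 1 probe, 68 had identical values over their probes within 1e-06, ACT1 with 49 probes among them. Those may be averages made before the values were deposited, which the sources used here do not state. Probes of a gene were averaged, then the scans of a replicate that gave a value, and genes with a value in all 3 replicates were kept (3613). No genome build is named for these arrays, so no coordinates are given.

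The design, the gene lists and the rule for named genes were fixed before the data were examined. Each gene's mean log2 ratio was tested against 0 with limma's moderated test (lmFit, eBayes; limma 3.58.1 in R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, on 2 residual degrees of freedom and 4.43 from the prior. The untreated RNA enters only as the other channel of each array. For lists with at least 4 measured members, limma's camera with a preset inter-gene correlation of 0.01 compared the members with all other genes, adjusted over the 32 lists tested of 36 fixed. Camera with an estimated correlation and the rotation test fry, which asks whether a list's genes move one way on balance, stand beside it. The estimated form uses the 2 residual degrees of freedom of the fit, while the preset form does not. A further run, chosen after seeing the data, gave each list its estimated correlation, set to 0 where negative, with the degrees of freedom of the preset form. Both forms with an estimated correlation were also run after section-centring and after the loess described below. The scans were compared with limma on the difference of high minus low power within each replicate. Older names in the lists were mapped through the synonyms of the reference table.

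Named genes were to be the 12 largest and 12 smallest means among genes past the threshold. Where fewer than 6 passed in a direction, the rule took the 6 with the smallest unadjusted p, named as not past the threshold, which applied in both directions. For each list described, it allowed up to 4 members with the largest absolute mean, called or not. MEH1 and the genes that lead after section-centring fall outside the rule, as is said where they stand.

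Array sections were read from the probe number, whose first digit gives a block and whose next pair of digits gives a row. This reading is inferred from the numbers and from the ratios, as no layout was used. Section-centring subtracts from each scan the median of its section, in sections with at least 5 genes, and a two-dimensional loess with a span of 0.05 over the same positions is a second version. Both were chosen after seeing the data.

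The alternatives were each scan power alone, all 6 scans with the replicate as a random block, median and quantile centring of the scans, genes in at least 2 replicates or in both scans of all 3, array weights, each replicate left out, a robust prior, other thresholds, an unmoderated statistic, a 2-fold rule, other list tests and 10000 random lists. Where values were missing or a block was fitted, camera's preranked form was used for the lists.

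The tests were run on simulated data for the comparison of thorium with untreated cells, with 3613 genes of which 200 were changed, in 5 runs. Changed genes were recovered in 4.4% of cases at a log2 change of 1, 73.2% at 2, 94.8% at 3 and 98.8% at 4, with 20 false calls of 698. The general stress list, shifted by 0.5, was found in 5 of 5 runs, and 0 other lists were called, leaving aside the trehalose and weak acid lists, which share genes with it. The simulated genes varied independently and held no position trend. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.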

Results

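Budding yeast of strain S288C, growing exponentially in rich glucose medium (YPD) at 25 °C, was exposed to thorium, an actinide metal, at 5 mM for 2 h. The polyA RNA of these cells was labelled with Cy5 and hybridised on the same array as Cy3-labelled RNA of cells grown for 2 h without thorium. The series holds 3 hybridizations, each of an independent biological sample, and each hybridization was scanned once at high and once at low laser power. The 6 scans are therefore 3 replicates, and there was no hybridization with the dyes exchanged. Of 6912 probes, the high power scans gave a value for 4198 in replicate 1, 5483 in replicate 2 and 5435 in replicate 3, and the low power scans for 2782, 3780 and 4552. A value in all 3 replicates was had for 3613 named genes, and the number of arrays limits the precision of each. Ratios are given as Cy5 over Cy3, so that a value above 0 is likely higher RNA in thorium. That direction rests on the order of the channels in the labels, and the base of the logarithm was taken as 2 without being stated.

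The series asks how thorium is toxic to yeast, and the first comparison was between groups of genes in treated and untreated cells. Genes for cell wall mannoproteins of anaerobic growth, for phosphate uptake, for fatty acid and acetate use, for the general stress response and for the cell wall were higher as groups in thorium, as were genes for hexose transport and for the carbohydrate stores trehalose and glycogen. These calls are those of limma's camera with its preset correlation, and 0 of 32 lists passed in its other form (smallest adjusted p = 0.586 with an estimated correlation) or in the rotation test fry. Genes for ribosomal proteins of the cytosol, for the proteasome, for core histones and for protein folding were lower as groups. In all, 7 lists were higher and 4 were lower than the other genes among the 32 lists tested. The estimated form rests on 2 residual degrees of freedom, so few that a list can fail in it without correlated genes. DAN/TIR/PAU had an estimated correlation of -0.00380, below the preset 0.01. Its unadjusted camera p still went from 3.01e-05 in the preset form to 0.0509 in the estimated form. A list failing in the estimated form therefore cannot tell correlated genes from few replicates. With each list's estimated correlation and the degrees of freedom of the preset form, a setting chosen after seeing the data, 4 of the 11 passed, DAN/TIR/PAU, general stress, cell wall and ribosomal proteins. No single gene passed the threshold over all genes tested, so member values are given below without a call unless the count adjusted over the list alone is named. Such a count is adjusted within its own list only and not for the number of lists. The adjusted p given beside replicate medians below are camera's, which compare a list's members with the other genes. They do not test the replicate medians against 0 and do not measure their spread.

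The DAN/TIR/PAU list, mannoproteins that replace other wall proteins when oxygen is lacking, had the largest shift of the 11 called lists. Its median over 5 measured members, of 14 with a probe, was 0.82 on the log2 scale. All 5 were above 0, and 4 were above 0 in every replicate. Whether a member's having a value depended on its signal in thorium was not tested. The medians of the 3 replicates averaged 1.05 ± 0.26 (SD, n = 3; adjusted p = 0.000769; adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone 3 members rose, and adjusted over all genes 0 did. They were TIR1 at 2.45 ± 0.74, DAN1 at 2.06 ± 0.87 and PAU24 at 0.82 ± 0.22 (SD, n = 3), while TIR3 stood at 0.75 ± 0.95. TIR1 rests in part on 1 scan, since in replicate 1 it read 5.76 at high and 0.50 at low laser power. Members of this family have similar sequences, and their probes may not separate them.

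The phosphate starvation list, most of whose members serve phosphate uptake and storage, had a median of 0.74 over 13 measured members of 18 with a probe. Of these, 10 were above 0 and 6 above 0 in every replicate. Its replicate medians averaged 0.75 ± 0.39 (SD, n = 3; adjusted p = 0.00270; adjusted p = 0.586 with an estimated correlation). The members farthest from 0 were PHO84, the high-affinity phosphate transporter, at 1.84 ± 1.12, SPL2, a small regulator of low-affinity uptake, at 1.77 ± 1.17, and PHO5, a secreted acid phosphatase, at 1.45 ± 1.25. The fourth was CTF19 at 1.44 ± 1.88, a kinetochore protein. Adjusted over the list alone, 0 members passed. Over the 6 members measured in both scans of all replicates the median was 0.05, and over the 6 measured in all low power scans it was 0.11, and the call was lost in both. Without replicate 2 the median was 0.44, past the threshold.

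Among carbon metabolism genes, the list for gluconeogenesis, the glyoxylate cycle and fatty acid oxidation had a median of 0.62 over 11 measured members of 27 with a probe. Of the 11, 9 were above 0 and 3 above 0 in every replicate. Its replicate medians averaged 0.63 ± 0.46 (SD, n = 3; adjusted p = 0.0141; adjusted p = 0.680 with an estimated correlation). ACS1, an acetyl-CoA synthetase, stood at 1.31 ± 1.27, FAA2, a fatty acyl-CoA synthetase, at 1.10 ± 0.65, CAT8, an activator of gluconeogenic genes, at 0.97 ± 0.35, and YAT2, a carnitine acetyltransferase, at 0.95 ± 1.53. All 14 measured members of the hexose transport list, of 21 with a probe, lay above 0 and 4 of them in every replicate, with a median of 0.36 and replicate medians of 0.38 ± 0.41 (SD, n = 3; adjusted p = 0.00246; adjusted p = 0.586 with an estimated correlation). For the gluconeogenesis and hexose lists too, whether a gene's having a value depended on its signal in thorium was not tested. HXT16 at 1.48 ± 1.44, HXT13 at 1.27 ± 1.15 and HXT9 at 0.85 ± 0.27 belong to the hexose transporter family by name. STD1, a regulator of glucose-responsive genes, was at 0.64 ± 0.62. The HXT genes are close paralogs, and HXT13 and HXT16 may share signal. In the trehalose and glycogen list 10 of 14 members were above 0 and 7 in every replicate, with a median of 0.48 and replicate medians of 0.25 ± 0.34 (SD, n = 3; adjusted p = 0.0141; adjusted p = 0.680 with an estimated correlation). GDB1 and GLC3, the glycogen debranching and branching enzymes, stood at 1.29 ± 0.51 and 1.12 ± 0.50, TSL1, a trehalose synthase subunit, at 1.01 ± 1.10, and the acid trehalase ATH1 at 0.94 ± 0.46. The array section of ATH1 had a median of 0.85, and after section-centring ATH1 stood at 0.09 ± 0.34. GDB1, GLC3 and TSL1 then stood at 1.10, 0.99 and 0.78. The median of this list was 0.23 over the 13 members measured in both scans of all replicates and 0.26 over genes in at least 2 replicates, past the threshold in both. Adjusted over the list alone, 0 members of these 3 lists passed. Without replicate 3 the hexose and the trehalose calls were lost (medians 0.18 and 0.22), and without replicate 2 the gluconeogenesis call was (median 0.36). Without replicate 1 the hexose median was 0.64. Over the 4 hexose members measured in both scans of all replicates the call was lost with a median of 0.55, higher than over all 14.

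The general stress list, genes shared by many stresses, had a median of 0.58 over 25 members, with 18 above 0 and 11 above 0 in every replicate. Its replicate medians averaged 0.40 ± 0.23 (SD, n = 3; adjusted p = 0.00162; adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone 3 members rose, and over all genes 0 did. These were the repressor XBP1 at 1.60 ± 0.78, the glutamate decarboxylase GAD1 at 1.14 ± 0.21 and SOL4, a 6-phosphogluconolactonase, at 1.14 ± 0.21 (SD, n = 3). The catalase CTT1 stood at 1.10 ± 0.70. This list shares 6 measured genes with the trehalose and glycogen list, so the shifts of both are not separate. The cell wall list had a median of 0.47, with 17 of 25 members above 0, 12 in every replicate, and replicate medians of 0.34 ± 0.14 (SD, n = 3; adjusted p = 0.00190; adjusted p = 0.586 with an estimated correlation). Its leading members were the mannoprotein CWP1 at 1.52 ± 0.68, the wall-anchored protease YPS1 at 1.12 ± 0.28, and the structural wall proteins SED1 at 1.06 ± 0.50 and CIS3 at 1.06 ± 0.45. Adjusted over the list alone, 0 of them passed. The median of the cell wall list was 0.31 without replicate 1 and 0.21 without replicate 3, past the threshold in both cases.

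Of 113 measured genes for cytosolic ribosomal proteins 86 lay below 0, and 50 lay below 0 in every replicate. The median was -0.37, and the replicate medians averaged -0.37 ± 0.12 (SD, n = 3; adjusted p = 0.000769; adjusted p = 0.586 with an estimated correlation). RPL35B at -1.65 ± 1.23, RPS6A at -1.51 ± 1.40, RPS21B at -1.36 ± 0.09 and RPL9A at -1.35 ± 0.62 lay farthest from 0, and adjusted over the list alone 0 members passed. Replicate 1 read -3.07 for RPL35B and -3.13 for RPS6A, and without it their means were -0.94 and -0.70, nearer to 0 than that of RPS21B at -1.39. Most of these genes occur as near-identical pairs whose probes may cross-hybridise. In the proteasome list 25 of 27 members lay below 0 and 12 in every replicate, with a median of -0.42 and replicate medians of -0.56 ± 0.17 (SD, n = 3; adjusted p = 0.00131; adjusted p = 0.586 with an estimated correlation). Adjusted over the list alone 2 members fell, the core particle subunits PRE10 at -1.34 ± 0.30 and PRE3 at -1.31 ± 0.26, and over all genes 0 did. The regulatory particle subunits RPT3 and RPN9 stood at -1.17 ± 0.72 and -0.98 ± 0.27. Without replicate 2 the medians were -0.21 for ribosomal proteins and -0.63 for the proteasome, and without replicate 3 the proteasome median was -0.27, all past the threshold. The ribosomal median was -0.48 in the high power scans alone and -0.24 in the low power scans alone, past the threshold in both.

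All 6 measured core histone genes lay below 0 and 4 in every replicate, with a median of -0.68 and replicate medians of -0.66 ± 0.50 (SD, n = 3; adjusted p = 0.0404; adjusted p = 0.761 with an estimated correlation). HHF2, a gene for histone H4, fell when adjusted over the list alone, at -1.15 ± 0.29, and 0 passed over all genes. HTB2, HHT1 and HHF1 stood at -0.77 ± 0.47, -0.76 ± 0.56 and -0.61 ± 0.48, and the paired histone genes may share signal. After section-centring the means were -0.55 for HHF2, -0.25 for HTB2, -0.30 for HHT1 and -0.29 for HHF1. In the protein folding list 17 of 21 members lay below 0 and 8 in every replicate, with a median of -0.27 and replicate medians of -0.30 ± 0.18 (SD, n = 3; adjusted p = 0.0479; adjusted p = 0.697 with an estimated correlation). BTN2, which sorts misfolded proteins, stood at -2.33 ± 1.51, FES1, an exchange factor of Hsp70, at -1.37 ± 1.01, the Hsp90 gene HSC82 at -0.71 ± 0.43 and the J-domain gene APJ1 at -0.71 ± 0.88, and adjusted over the list alone 0 passed. Both calls were lost without replicate 2 (medians -0.43 and -0.30), in the low power scans alone (-0.57 and -0.23), over genes measured in both scans of all replicates (-0.68 and -0.28) and after a two-dimensional loess over array position (-0.39 and -0.21), a step chosen after seeing the data. The folding call was also lost without replicate 3 (median -0.08) and against 10000 random lists, where its median stood at percentile 8.72. It was -0.46 without replicate 1.

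**Figure D1:**
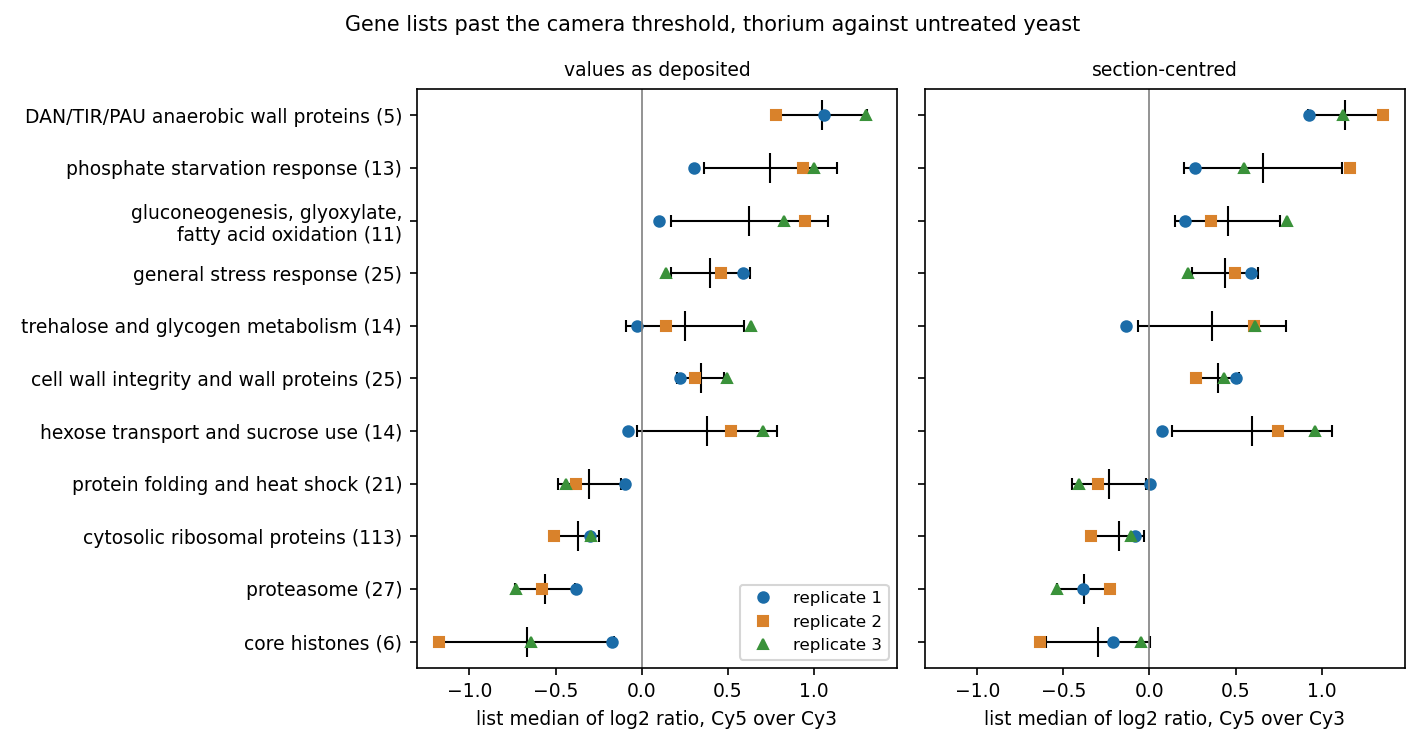
Median log2 ratio (Cy5 over Cy3) of each called gene list on the x axis, with the number of measured genes in brackets and 1 point per replicate; the upright bar is the mean of the 3 replicate medians and the whisker its SD. In the values as deposited replicate 1 lies nearest to 0 for 8 of the 11 lists, and for 2 of these, hexose transport and trehalose, it lies on the other side of 0 (-0.08 and -0.03), and the histone median moves from -0.68 to -0.29 when the values are centred by array section.

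A further 21 lists did not pass, and their members had values on both sides of 0. Of the metal lists, the iron regulon had a median of -0.11 over 16 members (adjusted p = 0.747), with 1 passing when adjusted over the list alone, the metal reductase FRE1, which fell. The copper list had a median of -0.15 over 6 members (adjusted p = 0.747), with 1 passing when adjusted over the list alone, the metallothionein CRS5 at 1.26 ± 0.39, while the metallothionein gene CUP1-2, which has a near-identical copy, was at -0.66 ± 1.11. The zinc list had a median of -0.14 over 8 members (adjusted p = 0.747). The oxidative stress list had a median of -0.04 over 21 members (adjusted p = 0.747), with SOD2 passing when adjusted over the list alone. The weak acid list had a median of 0.56 over 6 members (adjusted p = 0.0890), with YRO2, a plasma membrane protein gene, at 1.57 ± 0.32 and 1 member passing when adjusted over the list alone. It passed in the low power scans (median 0.69), without replicate 3 (median 0.55), with all 6 scans and a replicate block (median 0.56), and against 10000 random lists, but not in the form that estimates the correlation (adjusted p = 0.586 with an estimated correlation). The nitrogen catabolite list had a median of -0.51 over 10 members (adjusted p = 0.873), but a mean of -0.01 and replicate medians of -0.17, -0.08 and 0.09. Its 1 member to pass when adjusted over the list alone was DAL80, a GATA repressor gene, at 2.14 ± 0.91. In the multidrug list (median 0.06, 10 members, adjusted p = 0.605) the sphingoid base transporter RSB1 passed adjusted over the list alone at 1.45 ± 0.24. In the calcineurin and alkaline list (median -0.20, 6 members, adjusted p = 0.934) YPS1 did.

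No member of the following lists passed when adjusted over the list alone. Median log2 ratios were -0.12 for ribosome biogenesis (46 members, adjusted p = 0.741), -0.23 for other amino acid synthesis (41, adjusted p = 0.108), -0.05 for sulfur assimilation (14, adjusted p = 0.741) and 0.48 for thiamine synthesis (6, adjusted p = 0.108). They were -0.22 for ergosterol synthesis (15, adjusted p = 0.660), -0.15 for glycolysis and fermentation (16, adjusted p = 0.888), 0.04 for the citric acid cycle (13, adjusted p = 0.934) and -0.27 for the respiratory chain (20, adjusted p = 0.741). They were 0.23 for the DNA damage response (11, adjusted p = 0.120), -0.15 for the unfolded protein response (16, adjusted p = 0.934) and 0.20 for autophagy and vacuolar proteases (10, adjusted p = 0.605). The G1/S list had a median of -0.33 (7, adjusted p = 0.330) and the G2/M list of -0.14 (17, adjusted p = 0.747). Ribosome biogenesis passed as lower without replicate 3 (median -0.40), and other amino acid synthesis without replicate 2 (median -0.27) and over genes in at least 2 replicates (median -0.28), all with the preset correlation (as deposited, adjusted p = 0.968 and 0.680 with an estimated correlation). On section-centred values these lists passed in the same leave-outs (medians -0.36 and -0.20). Without replicate 1, thiamine synthesis (0.32) and G2/M (-0.24) passed on section-centred values, also with the preset correlation. The test's direction opposed the sign of the median for the copper, sulfur, oxidative stress, citric acid and calcineurin lists, whose means were 0.07, 0.06, 0.00, -0.11 and -0.05. The lists for arginine synthesis (3 members, median -0.38), a-type mating and pheromone genes (2, -0.32), alpha-type mating genes (3, -0.14) and sporulation (1, -0.01) were too short to test.

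The second comparison was between thorium and untreated cells gene by gene. The genes with the strongest evidence of higher RNA were TIR1, at 5.48-fold, MIG2, a repressor of glucose-repressed genes, at 4.55-fold, and SOD2, the mitochondrial superoxide dismutase, at 3.52-fold. Those with the strongest evidence of lower RNA included FRE1, a ferric and cupric reductase, at 3.11-fold lower, and CUR1, which sorts misfolded proteins like its paralog BTN2, at 3.49-fold lower. All were on the same side of 0 in 3 of 3 replicates, and none passed the threshold (adjusted p = 0.271 for each). Of 3613 genes 0 were called by limma, and 0 by the unmoderated one-sample statistic. At an unadjusted p under 0.05 limma gave 499 genes, 206 higher and 293 lower, against 180.65 expected by chance, and the unmoderated statistic gave 369. The same sign in all 3 replicates was seen for 1393 genes, 38.6%, where independent replicates would give 25% by chance. Replicates 2 and 3 share a position trend on the array that replicate 1 does not, described further on. The values to be had by chance, here and for the unadjusted p, are therefore not known. In every replicate 24 genes were at least 2-fold higher and 17 at least 2-fold lower as deposited, and 15 and 1 after centring by array section.

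On the log2 scale TIR1 (YER011W) stood at 2.45 ± 0.74, MIG2 (YGL209W) at 2.19 ± 0.63 and SOD2 (YHR008C) at 1.82 ± 0.41 (SD, n = 3). SLZ1 (YNL196C), a sporulation-specific gene, was at 1.63 ± 0.33, AHC1 (YOR023C), of the ADA histone acetyltransferase complex, at 1.58 ± 0.08, and GAS5 (YOL030W), a glucanosyltransferase of the wall, at 1.54 ± 0.23. On the lower side CUR1 (YPR158W) stood at -1.80 ± 0.79, IRC7 (YFR055W), a cysteine beta-lyase, at -1.64 ± 0.61, and FRE1 (YLR214W) at -1.64 ± 0.24. CTH1 (YDR151C), an RNA-binding protein of iron limitation, was at -1.61 ± 0.57, the prefoldin subunit GIM3 (YNL153C) at -1.40 ± 0.33 and RPS21B (YJL136C), of the small ribosomal subunit, at -1.36 ± 0.09. The array sections of these probes had medians of the same sign as the genes. The section median was 0.85 for AHC1, 0.65 for SLZ1, 0.63 for GAS5, 0.60 for MIG2, 0.42 for TIR1 and 0.20 for SOD2. It was -0.60 for FRE1, -0.49 for both GIM3 and RPS21B, -0.46 for CTH1, -0.37 for IRC7 and -0.31 for CUR1. After subtraction of these medians scan by scan, a step chosen after seeing the data, the means were 2.03 for TIR1, 1.61 for SOD2, 1.54 for MIG2, 0.92 for GAS5, 0.77 for SLZ1 and 0.73 for AHC1. They were -1.51 for CUR1, -1.26 for IRC7, -1.14 for CTH1, -0.98 for FRE1, -0.91 for GIM3 and -0.87 for RPS21B. Without replicate 1 limma called 191 genes as deposited, 81 higher and 110 lower, and 0 with the values centred by section.

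**Figure D2:**
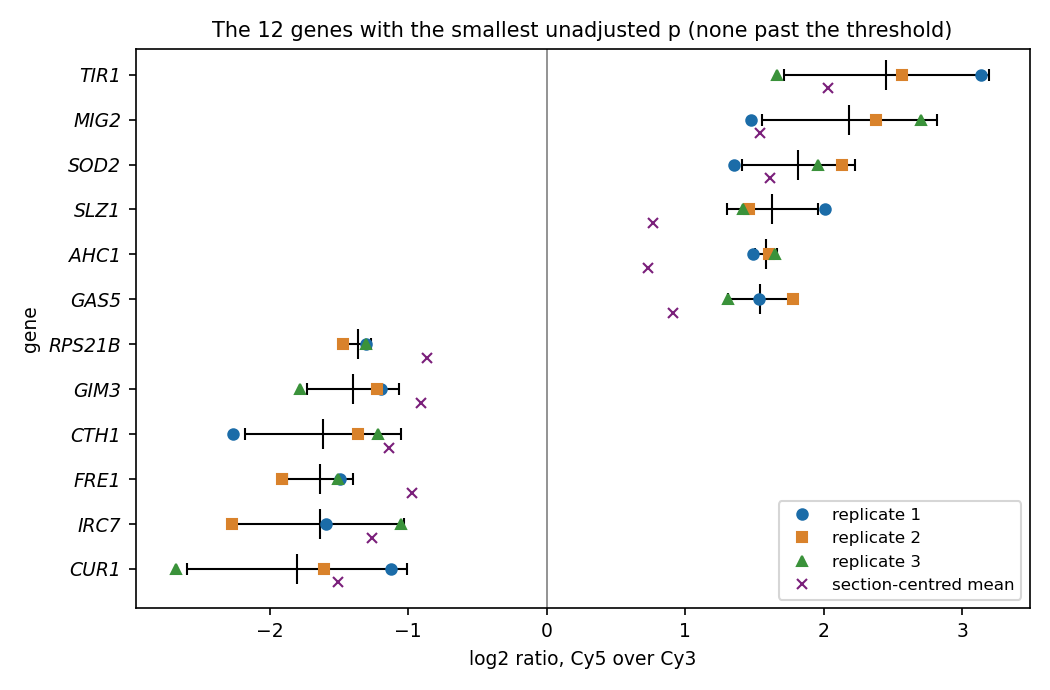
Log2 ratio (Cy5 over Cy3) on the x axis for the 12 genes with the smallest unadjusted p, 6 per direction; points are the 3 replicates, the upright bar their mean, the whisker its SD, and the cross the mean after centring by array section. All 36 points lie on the side of their gene's mean, and for AHC1 the cross lies at 0.73 against a mean of 1.58.

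Across genes the replicates did not resemble each other equally. Pearson's correlation over the 3613 genes, which are not independent replicates, was 0.56 between replicates 2 and 3, 0.09 between replicates 1 and 2 and 0.02 between replicates 1 and 3. The probe numbers place each probe in 1 of 192 array sections of 36 probes, and the section accounted for 40.7%, 46.2% and 43.1% of the variance of the gene ratios in replicates 1, 2 and 3. In 100 permutations of the genes over sections the highest share was 1.33%, 1.01% and 0.98%. Section medians ran from -1.51 to 2.38 in replicate 1, from -1.18 to 1.22 in replicate 2 and from -1.25 to 0.92 in replicate 3. With the ratios centred by section the correlations were 0.46, 0.32 and 0.24 in the same order, 0 genes were called, and 10 of the 11 called lists passed in the same direction with the preset correlation, all but the core histones. With an estimated correlation 0 lists passed after centring (smallest adjusted p = 0.670 with an estimated correlation). After this centring the list median was 1.19 for DAN/TIR/PAU (1.27 after the loess), 0.46 for phosphate starvation, 0.32 for general stress, 0.27 for trehalose and glycogen, 0.57 for hexose transport and -0.22 for ribosomal proteins.

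**Figure D3:**
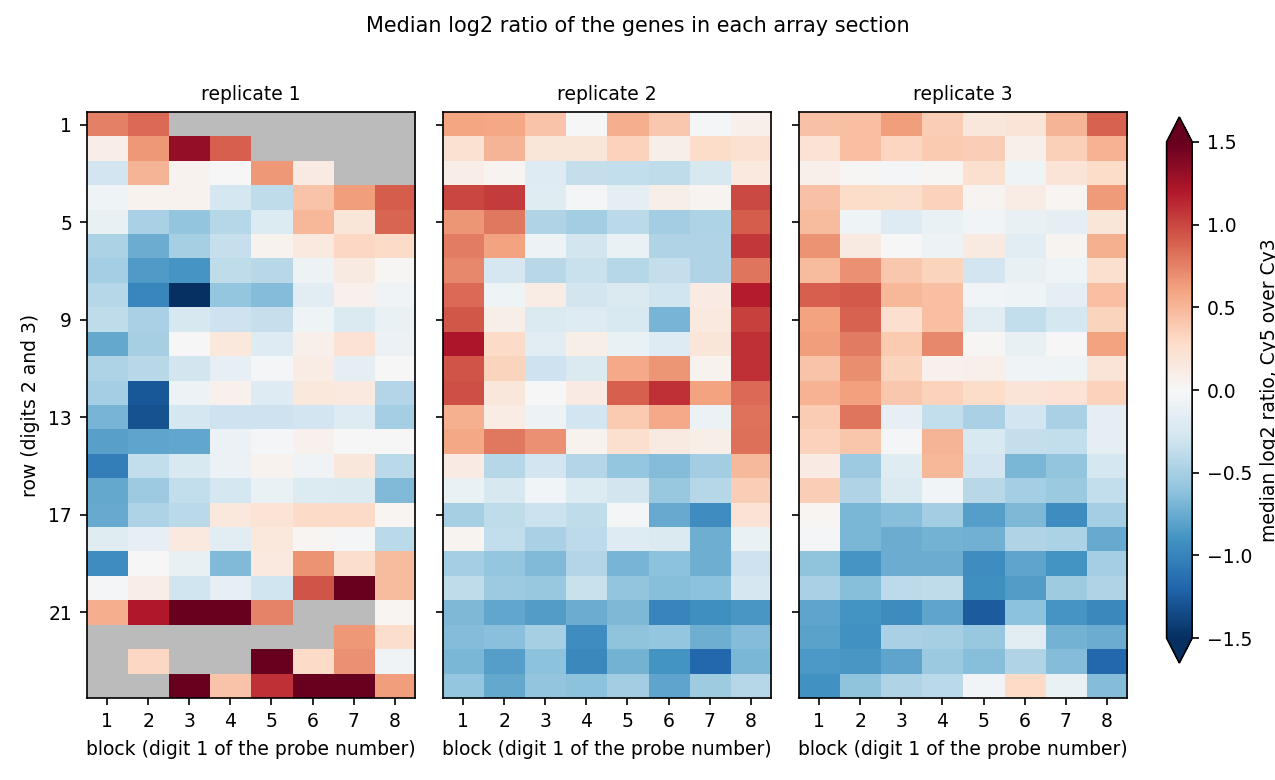
Median log2 ratio (Cy5 over Cy3) of the named genes in each array section, by the block (x axis) and row (y axis) that the probe number gives, for the 3 replicates; grey sections held fewer than 5 such genes and the colours end at 1.5 in either direction. Replicates 2 and 3 share low medians in the rows with high numbers, where several sections of replicate 1 are high.

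The third comparison was technical, between both scans of each hybridization, which hold the same RNA. TIR1 and MEH1, a gene for a vacuolar membrane protein, were called as higher at high than at low laser power. TIR1 differed by 5.26, 0.74 and -0.07 on the log2 scale in replicates 1, 2 and 3 (adjusted p = 5.64e-10), and MEH1 by 3.02, 1.20 and 0.20 (adjusted p = 4.79e-05). These were 2 of the 2108 genes measured in all 6 scans, and MEH1 is named here because it was called in this comparison. The mean differences were 1.98 ± 2.87 for TIR1 and 1.48 ± 1.43 for MEH1 (SD, n = 3), so TIR1's was within its own spread and MEH1's about equal to it. The fit gave all genes 1 common SD of 0.47, on which both calls rest. After each scan was centred on its median the differences were 2.06 and 1.56, no smaller, but the fit no longer used a common SD and both calls were lost. Without replicate 1 they were 0.33 and 0.70, and both calls were lost. Correlations between both scans of a hybridization across genes were 0.78, 0.76 and 0.93 in replicates 1, 2 and 3.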

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

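Section-centring, the loess, the run over all probes and the estimated correlation with the degrees of freedom of the preset form or after a position correction were chosen after seeing the data, and the other settings before. The count of called genes was 0 in every setting run except 4. Leaving out each replicate gave 0 to 191 genes, the highest without replicate 1, and 41 genes met the 2-fold rule in all 3 replicates without a test, 24 higher and 17 lower, against 16 on section-centred values, 15 higher and 1 lower. Section-centred values gave 0 to 8 genes with a replicate left out, 8 without replicate 3 and 0 without replicate 1 or 2. Of the 191 genes, 117 had the same sign in replicate 1 (61.3%), and the median of their array sections in replicates 2 and 3 was 0.52 for the higher and -0.73 for the lower genes. The count of called lists, 11, fell to 7 in the low power scans, where 28 lists could be tested, and to 5 over genes measured in both scans of all 3 replicates, where 27 could. In both, the DAN/TIR/PAU and gluconeogenesis lists had too few members to test, and the phosphate list no longer passed, with medians of 0.11 and 0.05. Core histones (-0.57 and -0.68) and folding (-0.23 and -0.28) no longer passed either, against medians of -0.68 and -0.27 over all genes, nor did hexose transport over genes in both scans (0.55). The count was 0 with an estimated correlation, where the smallest adjusted p was 0.586, and 0 by fry, where it was 0.0661. By fry 8 lists had an unadjusted p under 0.05. The smallest p by fry belonged to the DNA damage and G1/S lists, which camera did not call, and thiamine synthesis was also among the 8. Of the called lists only DAN/TIR/PAU, ribosomal proteins, proteasome, general stress and cell wall were among them. The cause for fry was not tested. With the estimated correlation and the degrees of freedom of the preset form the count of called lists was 4. Of these, 3 were higher (DAN/TIR/PAU, general stress, cell wall) and 1 lower (ribosomal proteins). After section-centring and after the loess it was 0 with an estimated correlation, with smallest adjusted p of 0.670 and 0.524, and 4 in each with the degrees of freedom of the preset form, DAN/TIR/PAU, cell wall and proteasome in both. The remaining list was phosphate starvation after section-centring and general stress after the loess, and ribosomal proteins passed in neither. In the other settings the count of called lists stayed between 9 and 12. Against 10000 random lists it was 11, 8 higher and 3 lower, with weak acid gained and protein folding lost. Leaving out each replicate gave 9 to 11 lists, and 10 to 12 on section-centred values. Two-dimensional loess gave 7 higher and 2 lower, losing core histones and protein folding, against 7 and 4 as deposited. With all 6 scans and the replicate block 12 lists and 0 genes passed. No paired analysis of separate groups was possible because each array already holds both conditions. Of 271 values of the called lists under the alternatives, 184 kept direction and side of the threshold, 87 kept direction only and 0 turned. Settings that changed only the list test reused the same gene means, so the list medians were fixed there. Of 876 values of 54 named genes 873 kept their sign. On section-centred values RPS6A stood at 0.0388 without replicate 1, and ATH1 at -0.0980 and HTB2 at 0.0720 without replicate 2, each with the sign turned, and the cause was not tested. The 2 genes called between scans became 0 when scans were median-centred and 0 when section-centred, and 0 to 2 with a replicate left out, 0 without replicate 1. Their mean differences were 1.98 (TIR1) and 1.48 (MEH1) as deposited, 2.06 and 1.56 median-centred and 1.74 and 1.24 section-centred. With centred scans the calls were thus lost with the common SD of the fit rather than with the differences. Without replicate 1 the fit kept a common SD, of 0.42, and the differences fell to 0.33 and 0.70. The median of all gene means was -0.09 as deposited and -0.02 after median-centring, a shift of 0.07. Array weights were 0.41, 1.46 and 1.65 for replicates 1, 2 and 3. Signal over background was not used here, and the share of probes with a value, lowest in replicate 1, is what limits the gene set.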

Other observations

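The tests on position, on the likeness of replicates, on dyes, on correlation with the preset form's degrees of freedom or after a position correction and on the lengths of all called lists were chosen after the results were seen, while those on probe placement, on the length of ribosomal protein genes and on mitochondrial ribosomal proteins were chosen before their results. With the ratios centred by array section, a step and a set of genes chosen after their values were seen, the gene with the smallest unadjusted p was RSB1, a transporter gene for sphingoid bases, at 1.75 ± 0.17 on the log2 scale (SD, n = 3). The repressor XBP1 stood at 1.70 ± 0.25, SOD2 at 1.61 ± 0.30, the uncharacterised YDR262W at 1.43 ± 0.08 and BTN2 at -2.18 ± 0.72, each with an adjusted p of 0.112. Among the 20 genes with the smallest unadjusted p were the wall protein genes SED1 at 1.57 ± 0.56, PAU24 at 1.24 ± 0.12, PIR3 at 1.16 ± 0.07 and the wall protease gene YPS1 at 1.13 ± 0.16, named here without a test of whether wall genes are frequent among the 20. The amino acid permease GAP1 stood at 1.41 ± 0.43 and the acetaldehyde dehydrogenase ALD6 at 1.41 ± 0.43. BTN2 and its paralog CUR1, at -1.51 ± 0.51, both act in sorting misfolded proteins. None passed the threshold, and the same sign in all 3 replicates was seen for 1596 genes (44.3%), against 1393 as deposited.

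Genes for mitochondrial ribosomal proteins, a group outside the fixed lists, were tested for a shift like that of the cytosolic ones. Of 45 measured, 31 lay below 0, with a median of -0.18 and replicate medians of -0.29 ± 0.03 (SD, n = 3). Camera gave an unadjusted p of 0.0384 with the preset correlation and 0.131 with an estimated one. Random lists matched on gene length had a median as low in 30.2% of draws, so short genes alone may account for this shift. Across 3611 genes the mean ratio correlated with gene length with a Spearman coefficient of 0.12, and of 0.09 after section-centring. The estimated correlation within lists was -0.00380 for DAN/TIR/PAU and -0.00705 for general stress, below the preset 0.01. All other called lists lay above 0.01, at 0.0180 for cell wall and 0.0272 for ribosomal proteins. It was 0.116 for the proteasome, 0.159 for protein folding, 0.160 for phosphate starvation and 0.185 for hexose transport. The highest were 0.216 for trehalose and glycogen, 0.261 for gluconeogenesis and 0.850 for the core histones. The preset value thus lay below the estimate for most called lists. With such estimates and the degrees of freedom of the preset form 4 of the 11 called lists passed as deposited. After section-centring 4 passed and after the loess 4, with DAN/TIR/PAU and cell wall in all of these.

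The first pattern is that ratios follow the place of the probe on the array. Neighbouring sections had correlated medians, at 0.618 in the replicate with the lowest value, which is consistent with a smooth trend of hybridization or scanning that a LOWESS on intensity would leave in place. Printing of related genes side by side was argued against, since list members shared a section 0.939 times as often as in shuffled layouts. The section medians correlated at 0.65 between replicates 2 and 3 and at -0.29 and -0.32 between replicate 1 and the others. Whether slide, washing or scanner made the trend was not tested, and no biological explanation was tested.

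The second pattern is that replicate 1 differs from replicates 2 and 3. The gap between the correlation of replicates 2 and 3 and the mean of the other pairs was 0.50, and section-centring narrowed it by 0.322, so the position trend may be part of the cause. It left a gap of 0.178, with a bootstrap interval from 0.138 to 0.217, so this trend as centred is not the whole cause. Genes missing from a scan were not the whole cause either, as those measured in both scans of all replicates had a gap of 0.424 (0.333 to 0.518). Having a value in both scans only stands in for brightness, which was not used here. Dim spots as the whole cause therefore stay open. For reversed dyes in replicate 1, its lowest correlation with the others after centring was 0.243 (0.204 to 0.278). That value cannot decide, since a dye bias of single genes keeps its sign when the dyes are reversed. Reversed dyes and a difference between the cultures themselves stay open.

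The third pattern is the shift of the fixed lists. The position trend was argued against as its whole cause by the 9 of 11 lists that passed after section-centring and after the loess with the preset correlation. As deposited 11 of 11 did, and with an estimated correlation 0 passed in any of these. As part of the cause the trend stays open. Replicate medians of ribosomal proteins went from -0.37 ± 0.12 to -0.18 ± 0.14 after section-centring. With estimated correlations and the preset form's degrees of freedom, camera passed ribosomal proteins after neither correction (adjusted p = 0.258 and 0.0740). General stress did not pass after section-centring in that form (0.0660). As the whole cause the trend stays open for the core histones and protein folding. Core histone replicate medians went from -0.66 ± 0.50 to -0.30 ± 0.30 after section-centring. The list median became -0.29, a smaller shift that no longer passed. Protein folding passed after section-centring (median -0.24) and not after the loess (-0.21), against -0.27 as deposited. Gene length was argued against by 9 of 11 called lists with medians outside the central 95% of length-matched lists. The exceptions were hexose transport and protein folding. For ribosomal proteins gene length was argued against by a share of 0.01% as low, the smallest the draws can give. Their median was -0.37 against -0.12 for matched lists. Lengths were those of genes in the reference table. The length of the mRNA was not matched, so a bias by mRNA length stays open for ribosomal proteins. A dye bias of single genes cannot be told apart from thorium, as 0 hybridizations had the dyes exchanged, and turning the sign of replicates gives only 4 patterns, too few for a share under 0.05: the real one called 11 lists and the highest other 5 (1 of 4 as large), and 0 genes against 0 (4 of 4). A response to thorium is a hypothesis that these tests leave open beside dye bias and correlation between the genes of a list. This holds for DAN/TIR/PAU and cell wall too. They passed with estimated correlations and the preset form's degrees of freedom, but those correlations were estimated from 3 replicates. On the 2 residual degrees of freedom camera gave both an adjusted p of 0.586, and fry gave 0.0906 and 0.181. That camera form cannot decide, since on so few degrees of freedom a list can fail without correlated genes.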
